A study of Mus musculus with 15 samples.

How the data were processed

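Gene expression was measured by sequencing of total RNA from mouse hematopoietic progenitors. Per the labels, the cells were immortalized from fetal liver with an estrogen-dependent Hoxb8 construct, in a line with both copies of Ddx41 (the wild-type line) and a heterozygous line. Per the labels' protocols, they were infected with a retrovirus holding no insert (empty vector), wild-type DDX41 or DDX41 with the G173R or R525H substitution, kept for 2 days and sorted for GFP. RNA was isolated with a column kit and libraries were made with a stranded total RNA kit after removal of ribosomal RNA, per the labels' protocols. The 15 samples form 5 groups of 3, and the groups and the replicate numbers 1 to 3 were taken from the sample titles. The names of 12 of the deposited files carry the code of another group than the title of their sample; each file was assigned to the sample it is recorded for, and each group follows the title. Nothing states that the 3 samples of a group come from separate cultures, so p-values measure the spread between these samples, which may be technical.

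The authors deposited 1 table per sample with 55359 genes, made with RSEM per the file headers and the submitters' processing notes; the version of RSEM, the aligner and the genome build are not given in the sources used here. Per the file headers, each table holds the expected count, an estimate of the reads of a gene that RSEM assigns in part where reads match several genes, and between 6.26 and 6.92 percent of a library's genes had a value that was not whole. The same tables hold TPM and FPKM columns, normalized by the authors per the file headers; TPM was read only for Ddx41 and for the column totals, neither was used in a test, and FPKM was not used. The expected counts were not normalized by the authors, and their totals differed between libraries.

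Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes passed the filterByExpr function with the groups as given (14548 genes, holding 99.95 to 99.97 percent of each library's counts), and libraries were scaled by TMM (factors 0.9687 to 1.057). One quasi-likelihood model with the group as its only term was fitted to all 15 libraries, which share 1 estimate of the spread (common dispersion 0.0369). Each comparison is a contrast of that model with Benjamini-Hochberg adjustment over the genes tested; a gene was called changed at an adjusted p under 0.05, with no limit on fold change. Levels are CPM (counts scaled to a common library total) on TMM-scaled totals, given as mean ± SD of 3 libraries, and each SE is the log2 fold change over the square root of its F statistic. The 7 main comparisons are the heterozygous against the wild-type line, both with empty vector, each DDX41 vector against the empty vector in the heterozygous line, and the vectors against each other. Each DDX41 vector group was also compared with the wild-type line, and an F test asked for any difference among the 5 groups.

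Gene names are the symbols in the files. Genes were named by a rule set before the data were examined: Ddx41; among called genes with a symbol, at least 5 CPM in the higher group and all 3 libraries of 1 group above all 3 of the other, the 8 largest rises and 8 largest falls (5 of each between vectors), leaving out predicted gene models and pseudogenes; and up to 4 members with the smallest p of each list that passed its test or had at least 3 called members. Lists without a call are described by at most 2 members, with values only. Cep55, Stk4, Pak2, Ptprs, Dgat2, Man2c1 and Cc2d1b are named in some comparisons outside this rule and were chosen after their values were seen. The 29 gene lists, also set before the data were examined, cover blood lineages, innate immune and stress responses, the cell cycle, DNA damage, RNA and ribosome genes and metabolism; where a symbol occurred for more than 1 gene, the gene with the higher mean stood for it. Lists were tested against all other genes with camera (limma 3.58.1) on voom-weighted log2 CPM with a preset correlation of 0.01 and adjustment over the 29 lists; camera with an estimated correlation and fry were alternatives. Folds against a group with 0 counts were computed against a floor of 3 counts over the group, and intervals and floors cover counting error only (95 percent, exact binomial for ratios of counts). Chromosomes came from GENCODE M21, matched by unversioned identifier (14503 of the genes tested, 99.7 percent), and no coordinates were used.

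Replicate numbers were checked for pairing as the correlation, over genes, of the deviations of same-numbered libraries from their group means. All 3 correlations were above 0.1 for the heterozygous against the wild-type line with empty vector (0.358 to 0.49), G173R against empty vector (0.181 to 0.399), G173R and R525H against DDX41 (lowest 0.28 and 0.321) and G173R against R525H (0.287 to 0.643), and for these comparisons a fit with the number as a block is given where it changes a call. For DDX41 and for R525H against empty vector the lowest correlations were -0.027 and 0.0676, and the numbers were not taken to pair these libraries.

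Alternatives set before the data were examined were DESeq2's size factors or upper-quartile factors in edgeR, no filter on low counts, a filter of at least 1 CPM in 3 libraries, the replicate block, limma voom, DESeq2 1.42.0 (Wald test), a fit of only the 6 libraries compared, a 2-fold limit and leaving out each library. The fit without the third libraries and DESeq2's likelihood ratio test were added after seeing the data. The pipeline was tested on simulated counts for the 14548 genes with known changes: for the heterozygous against the wild-type line it recovered 42 of 100 genes changed 1.5-fold and 69 of 100 changed 2-fold and called 5 unchanged genes. For DDX41 against empty vector it recovered 41 and 82 and called 8, and for G173R against R525H 30 and 74 with 2 called. The simulated libraries were drawn independently, without the shared deviations of same-numbered libraries, so recovery in the real libraries may differ. Replicates were compared by chi-square over genes: the statistic per degree of freedom was 4.148 to 107.8 over the 15 pairs, so no pair differed by less than sampling noise.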

Results

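RNA from 15 samples of mouse hematopoietic progenitors was sequenced, 3 in each of 5 groups. One group is the wild-type line with empty vector (WT empty), and 4 groups are the heterozygous line with empty vector (Het empty), wild-type DDX41 (Het DDX41), G173R (Het G173R) or R525H (Het R525H). DDX41 is a DEAD-box RNA helicase, and both substitutions occur in its human form in myeloid neoplasms. Total expected counts, in the order of libraries 1 to 3, were 33668669, 36416176 and 37109795 for WT empty, 30947480, 35170636 and 32413483 for Het empty, and 49145873, 46362170 and 36766119 for Het DDX41. They were 27743681, 31599985 and 33948641 for Het G173R and 34982413, 40527116 and 22104066 for Het R525H. Groups follow the sample titles. The names of 12 deposited files give other group codes, under which the libraries called Het empty here would carry a DDX41 vector and those called Het G173R the empty vector, so what each result on a heterozygous group means rests on the titles. Between 17863 and 19506 genes had a count in each library, and mitochondrial genes took 2.158 to 2.987 percent of the counts.

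Ddx41 itself was lower in the heterozygous than in the wild-type line and was much alike in the 4 heterozygous groups. Its mean was 59.3 ± 3.9 CPM (SD, n = 3) in WT empty and 30.3 ± 2.3 in Het empty, 51.2 percent of the wild-type level. It fell by 0.97 on the log2 scale (SE 0.11, edgeR adjusted p = 0.000138), with all 3 libraries of Het empty below all 3 of WT empty. The means in Het DDX41, Het G173R and Het R525H were 33.1 ± 3.1, 33.3 ± 4.9 and 32.1 ± 2.8 CPM. Their log2 differences from Het empty were 0.13, 0.13 and 0.08, with 95 percent intervals of -0.12 to 0.37, -0.11 to 0.38 and -0.16 to 0.33 (adjusted p = 1 for each), so a rise of Ddx41 counts with any of the vectors was not detectable here. The counts do not tell whether the vectors' DDX41 would be counted under this gene.

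**Figure D1:**
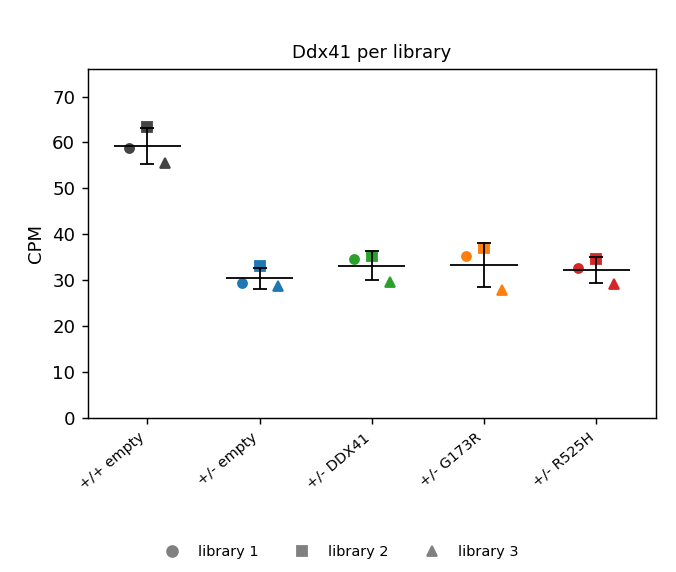
Ddx41 in CPM for each library of the 5 groups; horizontal bars are means and error bars SD of 3 libraries. WT empty averages 59.3 CPM and the 4 heterozygous groups average between 30.3 and 33.3.

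The heterozygous line with empty vector was compared with the wild-type line with empty vector to ask what differs between them. Each genotype has 1 line, so the loss of 1 copy of Ddx41 cannot be told apart from other differences between the lines. Of 9 tested genes of mast cells and basophils 5 fell in Het empty and none rose. Ms4a2, a chain of the high-affinity IgE receptor, was 4.51 ± 0.443 CPM against 27.6 ± 11.9 (log2 -2.61, SE 0.31, adjusted p = 0.000133). Cpa3, a mast cell carboxypeptidase, was 15.8 ± 1.3 against 46.4 ± 12.5 (log2 -1.55), and the proteases Cma1 and Prss34 fell by 2.73 and 1.77 on the log2 scale. Of 13 erythroid genes 2 fell; Gata1, an erythroid and mast cell transcription factor, was 1.14 ± 0.289 CPM against 3.97 ± 1.5 (log2 -1.80, adjusted p = 0.00605). Siglecf, a lectin of eosinophils, fell from 104 ± 7.27 to 52.5 ± 3.26 CPM. Among 12 lymphoid genes 2 fell: Cd79b, a part of the B cell receptor, by 0.94 and the recombinase gene Rag1 by 0.91. As lists, the mast cell, erythroid, eosinophil and lymphoid genes were lower with the preset correlation (adjusted p = 3.56e-07, 0.00594, 0.043 and 0.00761), and none passed with an estimated correlation (adjusted p = 0.08, 0.203, 0.194 and 0.194).

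Genes of neutrophils and monocytes moved both ways, more of them up. Of 18 neutrophil genes 2 rose and 1 fell, and 9 rose and 2 fell with the replicate block: S100a8, a calcium-binding protein, was 1.19 ± 0.0922 CPM against 0.0982 ± 0.0647, Fcnb, a granule lectin, 8.75 ± 3.91 against 1.41 ± 0.634, and the collagenase Mmp8 23.2 ± 10 against 177 ± 44.5. Elane, the neutrophil elastase, was 11.6 ± 4.94 against 2.41 ± 1.22 CPM, with an adjusted p of 0.085 and of 2.64e-07 with the replicate block. Of 18 monocyte genes 4 rose and 3 fell (7 and 3 with the block); Lyz2, lysozyme, was 13 ± 1.39 CPM against 3.01 ± 0.433 (log2 2.10, adjusted p = 1.1e-06), Csf2ra and the integrin Itgam rose by 1.19 and 1.15, and Fcgr1, an IgG receptor, fell by 1.09. Flt3, a cytokine receptor of early progenitors, fell from 366 ± 24.9 to 233 ± 23.8 CPM and was the 1 called gene of 18 stem and progenitor genes.

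**Figure D2:**
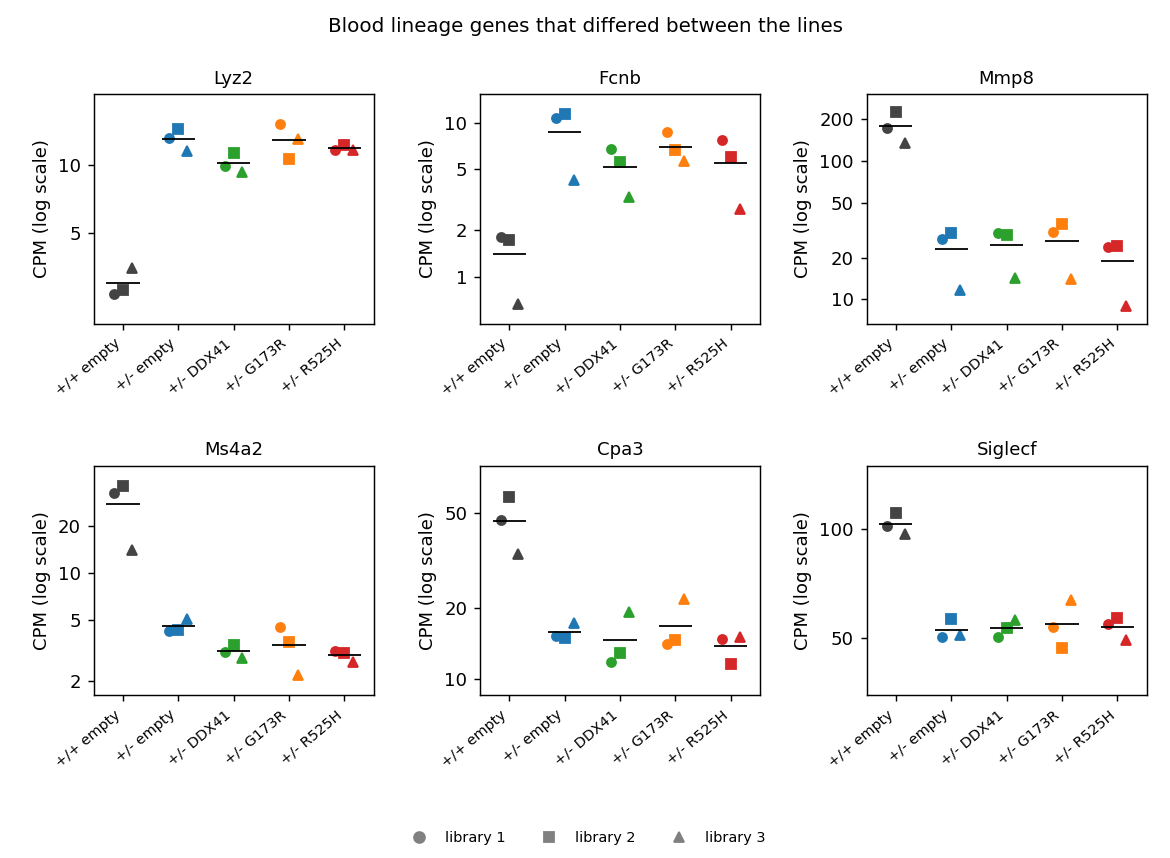
CPM on a log axis for 6 lineage genes in each library of the 5 groups, with bars at the means. Lyz2 averages 13 CPM in Het empty and 3.01 in WT empty, and Ms4a2 4.51 and 27.6.

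Innate immune genes fell in part. Of 17 genes of cytosolic DNA sensing 4 fell, Ddx41 among them; Aim2, a sensor of double-stranded DNA, was 12 ± 2.2 CPM against 23.3 ± 0.203, and Ifi203 and Ifi204 fell by 2.72 and 0.60 on the log2 scale. These last 2 have near-identical relatives, as histone and ribosomal protein genes do, so reads may be assigned between copies with uncertainty. Of 21 interferon-stimulated genes 2 fell and 1 rose (4 and 1 with the block): Rtp4, a chaperone, was 13.9 ± 2.85 CPM against 29.9 ± 4.16, Irf9, a subunit of the interferon transcription factor, fell by 0.45, and Mx2, a GTPase, rose by 0.95.

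The largest differences were genes with counts in 1 line and almost none in the other. Pja1, a ubiquitin ligase, was 28.9 ± 2.34 CPM in Het empty with no count in WT empty (at least 1060-fold higher). Zfp462, Pdlim1, Fgl2, Spon1 and Man1a also had no count in WT empty and were at least 877-, 435-, 421-, 391- and 378-fold higher, Agap1 was 23 ± 1.24 against 0.0433 ± 0.0749 CPM, and Tle3, a corepressor, had a ratio of 383 (131 to 1860). In the other direction Trim6 had no count in Het empty (at least 311-fold lower), Tmem141 had a ratio of 699 (125 to 27600), and Tshz3, Qsox1, Hsh2d, Mrgpra9 and Rab6b fell by 7.14, 5.22, 4.90, 4.23 and 4.15. Lama5, a laminin chain, was 2 ± 0.605 against 30.1 ± 5.74 CPM.

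Further lists without a called gene passed as higher with the preset correlation of the list test: glycolysis, stress response, histone, ribosomal protein, mitosis and immediate early genes (adjusted p = 0.000231, 0.00418, 0.00183, 0.00306, 0.0271 and 0.0271). None passed with an estimated correlation (adjusted p = 0.753, 0.634, 0.753, 0.811, 0.811 and 0.753), and the ribosomal protein list turned direction without WT empty 1. Of 22 glycolysis and hypoxia genes, 20 had a positive log2 fold change; Eno1, enolase, was 3910 ± 467 against 3120 ± 593 CPM and Pfkp, phosphofructokinase, 429 ± 47.6 against 320 ± 58.8, and 14 members rose with the replicate block. Of 18 genes of the unfolded protein and integrated stress responses 4 rose with the block; Asns, asparagine synthetase, was 213 ± 63.3 against 132 ± 37.2 CPM, and Psat1, of serine synthesis, 1100 ± 110 against 936 ± 117. All 20 histone genes had a positive log2 fold change (H2bc8 184 ± 26.2 against 128 ± 9.2 CPM), as had 67 of 75 ribosomal protein genes (Rps26 440 ± 46.6 against 385 ± 34.9), 19 of 23 genes of G2 and mitosis (Bub1 152 ± 6.69 against 136 ± 3.85) and 17 of 18 immediate early genes (Myc 288 ± 10.3 against 239 ± 13.3). Libraries numbered 3 stood apart in every group: against libraries 1 and 2, 21 of the 22 glycolysis genes, 13 of 18 immediate early and 12 of 18 stress genes were higher in them and 10 of 18 neutrophil genes lower. Called the other way were 1 immediate early, 2 stress and 3 neutrophil genes.

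In edgeR 532 of 14548 genes changed, 277 higher and 255 lower, with 1352 called with the replicate block and 1068 in libraries 1 and 2 alone. The list tests gave an adjusted p of 0.00281 for neutrophil, 0.000218 for DNA sensing and 0.00473 for interferon genes, and adjusted p = 0.194, 0.194 and 0.08 with an estimated correlation. The DNA sensing list holds Ddx41 itself, which the genotype lowers, and was not tested without it. With the block the eosinophil list had 0.0578.

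Adjusted over the list alone, 5 mast cell, 3 erythroid, 1 eosinophil, 3 lymphoid and 4 DNA sensing genes fell, 7 neutrophil genes rose and 2 fell, 6 monocyte genes rose and 3 fell, and 1 interferon gene rose and 2 fell. There 3 fetal liver, 1 megakaryocyte, 1 NF-kB and 1 stem gene also fell, and 1 antigen presentation gene and 1 p53 target went each way. With the block and all tested genes, 6 mast cell, 3 erythroid, 1 eosinophil, 4 DNA sensing and 2 megakaryocyte genes fell, 1 lymphoid gene rose and 3 fell, 1 fetal liver gene rose and 3 fell, 2 antigen presentation genes rose and 1 fell, and 2 NF-kB genes rose and 3 fell. There 1 DNA damage gene fell and 1 heat shock gene rose. The monocyte list had an adjusted p of 0.0587, stem and progenitor genes 0.318, megakaryocyte genes 0.139, antigen presentation 0.877 (1 rose), fetal liver and stroma 0.116 (2 fell), NF-kB 0.95, p53 targets 0.318 (1 rose, 1 fell), DNA damage 0.95, S phase 0.527 and snoRNA hosts 0.158. Ribosome biogenesis had 0.317, spliceosome 0.877, heat shock 0.131, cholesterol synthesis 0.24 (0.0133 with the block; adjusted p = 0.938 with an estimated correlation and 0.707 with both), mitochondrial mRNA 0.234 and sex-linked genes 0.763.

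Some of these calls were lost when 1 library was left out. The genes named here kept their direction in each such fit. Where the call was lost, the log2 fold change ran from -0.98 to -0.85 for Rag1 and from -0.47 to -0.38 for Irf9. Cd79b lost its call without WT empty 2 or 3 (adjusted p = 0.0705 and 0.0631) or Het empty 1 or 2 (0.0889 and 0.0822), and Rag1 without any of the 6 libraries (0.0801 to 0.184). Rtp4 lost it without WT empty 1 or 2 (0.0595 and 0.0777) or Het empty 1 or 3 (0.0554 and 0.0846), and Mx2 without WT empty 2 (0.0702) or Het empty 1 or 2 (0.0705 and 0.0544). Irf9 lost it without WT empty 1 or 2 (0.143 and 0.0762) or Het empty 1, 2 or 3 (0.0872, 0.164 and 0.0801). The erythroid list lost its call without WT empty 2 (0.0577) or Het empty 1 (0.0672), the eosinophil list without WT empty 1 or 2 (0.122 and 0.0577) or Het empty 1 or 3 (0.0887 and 0.0511), and the stress list without WT empty 1 (0.122) or Het empty 3 (0.0511). Mitosis genes lost it without WT empty 3 (0.515) or Het empty 2 (0.142), immediate early genes without WT empty 1 or 2 (0.176 and 0.381) or Het empty 3 (0.521), and ribosomal protein genes without WT empty 1, where the direction turned (0.518), or Het empty 2 or 3 (0.0572 and 0.148).

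Wild-type DDX41 was compared with empty vector in the heterozygous line to ask what restoring DDX41 changes. No gene passed in edgeR or with voom, 254 genes had an unadjusted p under 0.05, and DESeq2 called 3. Without effects a share of 0.05 of all genes tested is expected there, which is more than 254, so effects may be missed. Genes of the NF-kB response lay higher in Het DDX41, 18 of 21 with a positive log2 fold change: Nfkbia, the inhibitor of NF-kB, was 59.6 ± 1.39 against 48.2 ± 1.39 CPM (log2 0.31, adjusted p = 1) and Relb, an NF-kB subunit, 13.9 ± 1.5 against 10.7 ± 1.06. Of 75 ribosomal protein genes 68 lay higher (Rpl22 354 ± 22 against 320 ± 9.03 CPM), as did 21 of 22 glycolysis genes (Pgam1 1430 ± 62 against 1350 ± 97.2) and 12 of 13 mitochondrial mRNAs (mt-Co3 707 ± 234 against 524 ± 34.9) while among 4 eosinophil genes Prg2 was 0.481 ± 0.442 against 0.082 ± 0.118 and Siglecf 53.2 ± 2.99 against 52.5 ± 3.26. All 20 histone and all 20 cholesterol synthesis genes lay lower (H1f2 195 ± 27.6 against 247 ± 28.7). None of these lists passed with an estimated correlation (adjusted p = 0.568 or more).

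The list tests of this comparison gave adjusted p = 5.04e-06 for NF-kB, 1.66e-11 for ribosomal protein, 0.0259 for glycolysis, 0.0149 for mitochondrial, 0.0259 for eosinophil, 0.00296 for histone and 0.0259 for cholesterol genes. These became adjusted p = 0.731, 0.94, 0.974, 0.94, 0.568, 0.974 and 0.974 with an estimated correlation. There 1 NF-kB gene rose adjusted over the list alone. Without Het empty 1 the ribosomal protein, glycolysis and eosinophil lists had 0.113, 0.947 and 0.0919, and without Het empty 2 the mitochondrial and histone lists 0.131 and 0.104. Without Het empty 3 the eosinophil, mitochondrial and histone lists had 0.116, 0.295 and 0.242 and the cholesterol list turned direction (0.0551). Without Het DDX41 1 or 2 the cholesterol list had 0.127 and 0.345, and without Het DDX41 3 the mitochondrial and histone lists had 0.0583 and 0.26 and the glycolysis list turned direction (0.818).

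G173R was compared with empty vector in the heterozygous line. No gene passed in edgeR, with voom or with the replicate block, 88 had an unadjusted p under 0.05, and DESeq2 called 2. These 88 are also fewer than the share of 0.05 expected without effects, so effects may be missed. Among 4 eosinophil genes Prg2, the eosinophil major basic protein, was 0.656 ± 0.122 against 0.082 ± 0.118 CPM, and Prg3 0.29 ± 0.19 against 0.0399 ± 0.0346, both under 1 CPM, while Siglecf was 54.6 ± 8.4 against 52.5 ± 3.26. Of 23 mitosis genes 22 lay lower (Ccnb1, cyclin B1, 250 ± 25.7 against 270 ± 13.2 CPM, and Mki67 851 ± 61.8 against 897 ± 65.6), as did 29 of 30 ribosome biogenesis genes and all 20 cholesterol synthesis genes, while 69 of 75 ribosomal protein genes lay higher (Rpl11 854 ± 30.1 against 820 ± 22.8). The eosinophil list had an adjusted p of 0.000279, adjusted p = 0.0338 with an estimated correlation and 0.113 with an estimated correlation and the replicate block; fry gave 0.385. None of the other lists passed with an estimated correlation (adjusted p = 0.891).

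For mitosis, ribosome biogenesis, ribosomal protein and cholesterol genes in this comparison the list tests gave 0.00623, 0.000549, 0.000549 and 0.0384, and adjusted p = 0.891 with an estimated correlation for each. Adjusted over the list alone none of these 5 lists had a called gene. With the replicate block neutrophil, S phase and spliceosome genes also passed, each lower (0.0474, 0.02 and 0.00883; adjusted p = 0.891 for each with an estimated correlation and no block). Without Het G173R 3 the mitosis and ribosome biogenesis lists turned direction (0.992 and 0.00115), and without Het empty 2 they had 0.479 and 0.0558. The ribosomal protein list turned without Het empty 1 (0.101) and had 0.897 without Het G173R 2; the cholesterol list turned without Het empty 3 (0.00391) and had 0.638 and 0.554 without Het G173R 1 or 2.

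R525H was compared with empty vector in the heterozygous line, and 2 of 14548 genes fell in edgeR. Cep55, which acts in the last step of cell division, was 62 ± 5.66 against 94.3 ± 3.15 CPM (log2 -0.60, SE 0.08, adjusted p = 0.0308), and the kinase gene Pak2 136 ± 4.33 against 199 ± 9.84 (log2 -0.54, SE 0.07, adjusted p = 0.0187); in both all 3 libraries lay below. Host genes of small nucleolar RNAs lay higher, 14 of 17: Snhg1 was 344 ± 10.6 against 216 ± 13.3 CPM (log2 0.67, adjusted p = 0.0629) and Gas5 406 ± 30.7 against 278 ± 21.2 (adjusted p = 0.2). So did 26 of 30 ribosome biogenesis genes (Ncl, nucleolin, 1030 ± 106 against 873 ± 53.8 CPM), 56 of 75 ribosomal protein genes (Rpl30 493 ± 19.8 against 430 ± 22.7) and 30 of 35 spliceosome genes (Zrsr2, which recognises splice sites, 21.2 ± 0.654 against 16.9 ± 1.53). Of 18 stem and progenitor genes 16 lay lower (Flt3 196 ± 19 against 233 ± 23.8), and 10 of 12 lymphoid genes (Rag1 3.31 ± 0.564 against 5.28 ± 0.472). None of these lists passed with an estimated correlation (adjusted p = 0.286 or more).

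The list tests for R525H against empty vector gave adjusted p = 1.57e-06 for snoRNA hosts, 0.00766 for ribosome biogenesis, 0.000145 for ribosomal protein, 0.00463 for spliceosome, 0.00678 for stem and 0.00968 for lymphoid genes. With an estimated correlation these were adjusted p = 0.286, 0.864, 0.864, 0.864, 0.286 and 0.286. Of the snoRNA hosts 2 rose adjusted over the list alone, as did 1 monocyte gene, and 1 mast cell gene fell. An unadjusted p under 0.05 was reached by 725 genes, about the share of 0.05 of all genes tested that is expected without effects. DESeq2 called 60, voom 2 and edgeR 19 in libraries 1 and 2 alone. Cep55 lost its call without Het empty 1, 2 or 3 (0.108, 0.148 and 0.0695) or Het R525H 2 or 3 (0.103 and 0.113), and Pak2 without Het empty 1 (0.108) or Het R525H 2 or 3 (0.103 and 0.113). In these fits the log2 fold change ran from -0.63 to -0.54 for Cep55 and from -0.54 to -0.51 for Pak2. A fit of only the 6 libraries called neither (0.307 and 0.24). Without Het R525H 2 the lymphoid, ribosome biogenesis and spliceosome lists had 0.198, 0.112 and 0.0662, and without Het R525H 3 the stem and lymphoid lists 0.0967 and 0.0508. The ribosome biogenesis list had 0.0568 without Het R525H 1, the ribosomal protein list 0.828 without Het empty 1 and the spliceosome list 0.0629 without Het empty 3.

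G173R was compared with wild-type DDX41 to ask whether the substitution alters the effect of the vector. No gene passed in edgeR or with voom (smallest adjusted p = 0.4), 224 had an unadjusted p under 0.05, and DESeq2 called 3. Here, too, 224 is fewer than the share of 0.05 expected without effects. With the replicate block 1 gene rose: Cep55, chosen after its values were seen, was 97.7 ± 2.63 against 70.5 ± 5.97 CPM (adjusted p = 0.0288 with the block, 0.4 without). NF-kB genes lay lower in Het G173R, 20 of 21, with Nfkbia at 48.6 ± 3.93 against 59.6 ± 1.39 CPM and Il1b, interleukin 1 beta, at 5.67 ± 2.56 against 8.39 ± 1.01. Of 75 ribosomal protein genes 62 lay lower (Rpl7 1800 ± 15.8 against 1940 ± 48.5), as did 27 of 35 spliceosome genes (Sf3b1 733 ± 26.9 against 770 ± 16.3) and 16 of 23 mitosis genes (Bub1 151 ± 9.21 against 164 ± 4.84). All 20 histone genes (H2ac6 18.5 ± 8.69 against 12.1 ± 2.13) and 17 of 18 stem and progenitor genes (Kit 500 ± 10.3 against 470 ± 17.1) lay higher. With an estimated correlation no list passed (adjusted p = 0.536 or more).

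These 6 lists had adjusted p = 7.75e-05, 0.000338, 0.0108, 0.0287, 0.00527 and 0.00546 in that order, and adjusted p = 0.912 with an estimated correlation for all but the stem list (0.536). Adjusted over the list alone 1 NF-kB gene and 2 snoRNA hosts fell. With the block neutrophil genes (higher, 0.0037) and glycolysis genes (lower, 0.00206) also passed, each with adjusted p = 0.912 with an estimated correlation and no block. Without Het DDX41 3 the NF-kB, ribosomal protein and histone lists had 0.177, 0.771 and 0.468. Without Het DDX41 1 the mitosis and spliceosome lists had 0.706 and 0.706, and without Het DDX41 2 they had 0.229 and 0.712. Without Het G173R 3 these lists turned direction (0.847 and 0.119) and the ribosomal protein list had 0.156. Without Het G173R 2 the NF-kB and stem lists had 0.0904 and 0.095 and the histone list turned (0.0876), and without Het G173R 1 the NF-kB list had 0.101.

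R525H was compared with wild-type DDX41 for the same question. No gene passed in edgeR or with voom (smallest adjusted p = 0.0974). An unadjusted p under 0.05 was found for 581, fewer than the share of 0.05 expected without effects. DESeq2 called 35, and 59 passed with the replicate block. Among these 59, chosen after their values were seen, the kinase genes Stk4 and Pak2 were 251 ± 17.8 against 364 ± 51.2 CPM and 136 ± 4.33 against 183 ± 10.7 (adjusted p = 0.252 and 0.0974, and 0.00243 and 0.00255 with the block). The phosphatase gene Ptprs was 110 ± 11.3 against 150 ± 13.2, and Dgat2, of triglyceride synthesis, 112 ± 43.5 against 75.8 ± 31.7 (0.00243 and 0.000551 with the block). All 30 ribosome biogenesis genes lay higher (Nop56 462 ± 10.6 against 385 ± 78.1 CPM), as did all 17 snoRNA hosts (Snhg1 344 ± 10.6 against 264 ± 14.2), 30 of 35 spliceosome genes (Clk1 81.6 ± 8 against 68.7 ± 7.44) and 15 of 18 neutrophil genes (Ms4a3 204 ± 78.8 against 116 ± 53.8, adjusted p = 1, 0.00161 with the block). NF-kB genes lay lower, 17 of 21 (Nfkbia 46.3 ± 0.165 against 59.6 ± 1.39, adjusted p = 0.252, 0.0103 with the block), and 8 of 12 lymphoid genes (Rag1 3.31 ± 0.564 against 5.85 ± 1.43). With an estimated correlation no list passed (adjusted p = 0.564 or more).

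The list tests of R525H against DDX41 gave adjusted p = 5.44e-05 for ribosome biogenesis, 4.33e-05 for snoRNA hosts, 0.0364 for spliceosome, 0.0272 for neutrophil, 0.00296 for NF-kB and 0.0272 for lymphoid genes. With an estimated correlation these were adjusted p = 0.912, 0.564, 0.933, 0.564, 0.689 and 0.564. Adjusted over the list alone 1 NF-kB, 1 lymphoid, 1 stem, 1 mast cell and 1 DNA sensing gene fell and 1 monocyte gene rose. With the block antigen presentation (lower, 0.0167), heat shock (higher, 0.0325) and glycolysis genes (lower, 0.00701) also passed; these had adjusted p = 0.675, 0.933 and 0.933 with an estimated correlation and no block. Leaving out Het DDX41 3 let 2 genes pass, Stk4 and Pak2 (0.0449 each), and gave ribosome biogenesis 0.677, neutrophil 0.32, NF-kB 0.267, lymphoid 0.112 and spliceosome 0.677 with its direction turned. Without Het R525H 1 the spliceosome, neutrophil and NF-kB lists had 0.154, 0.0982 and 0.129, and without Het R525H 2 the spliceosome, neutrophil and lymphoid lists 0.217, 0.14 and 0.186.

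The substitutions were compared with each other, G173R against R525H, and 12 genes differed in edgeR, 8 higher and 4 lower in Het G173R. Chchd1, a mitochondrial ribosome protein, was 46.9 ± 9.43 against 24.1 ± 1.48 CPM (log2 0.96, SE 0.15, adjusted p = 0.0334), and Stk4 431 ± 26.6 against 251 ± 17.8 (log2 0.78, SE 0.11, adjusted p = 0.0215). Ptprs, Cep55, Aebp1 and Pak2 were higher by 0.68, 0.66, 0.65 and 0.51 on the log2 scale, and so were Man2c1 and Cc2d1b by 0.56 and 0.51; Pak2, Man2c1 and Cc2d1b were chosen after their values were seen. Snhg1 was 198 ± 16.7 against 344 ± 10.6 CPM (log2 -0.79, adjusted p = 0.0215), and the kinase gene Clk3, the ribosome rescue gene Hbs1l and Tlr4, the receptor of lipopolysaccharide, had log2 fold changes of -0.49, -0.41 and -0.41. Other snoRNA hosts lay the same way, 15 of 17 in all, with Gas5 at 270 ± 9.29 against 406 ± 30.7 CPM (adjusted p = 0.0947, 0.0105 with the block).

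Ribosome biogenesis genes lay lower in Het G173R than in Het R525H, 29 of 30 (Npm1 2620 ± 143 against 2920 ± 252 CPM), and spliceosome genes, 30 of 35 (Zrsr2 17.8 ± 0.802 against 21.2 ± 0.654). Libraries numbered 3 had 24 of these 30 and 27 of these 35 genes lower than libraries 1 and 2. Stem and progenitor genes lay higher, 16 of 18 (Flt3 258 ± 10.4 against 196 ± 19, adjusted p = 0.195, 0.00649 with the block), as did 9 of 12 lymphoid genes (Rag1 6.17 ± 2.11 against 3.31 ± 0.564, 0.272 and 0.0376 with the block) and all 8 antigen presentation genes (H2-DMa 18.6 ± 0.305 against 15.4 ± 1.5). No list of this comparison passed with an estimated correlation (adjusted p = 0.404 or more). The list tests gave adjusted p = 6.68e-06 for snoRNA hosts, 2.01e-06 for ribosome biogenesis, 3.9e-05 for spliceosome, 0.00256 for stem, 0.011 for lymphoid and 0.0292 for antigen presentation genes. With an estimated correlation these were adjusted p = 0.429, 0.729, 0.729, 0.404, 0.429 and 0.438. Adjusted over the list alone 2 snoRNA hosts, 1 monocyte and 1 interferon gene fell, and 1 stem, 1 lymphoid, 1 mast cell, 1 interferon and 2 DNA sensing genes rose. With the block neutrophil (0.0443), stress response (0.0295) and heat shock genes (0.00512) also passed as lower and megakaryocyte (0.0204), immediate early (0.0173) and histone genes (0.0382) as higher. Without a block and with an estimated correlation these had adjusted p = 0.73, 0.922, 0.729, 0.922, 0.922 and 0.922.

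**Figure D3:**
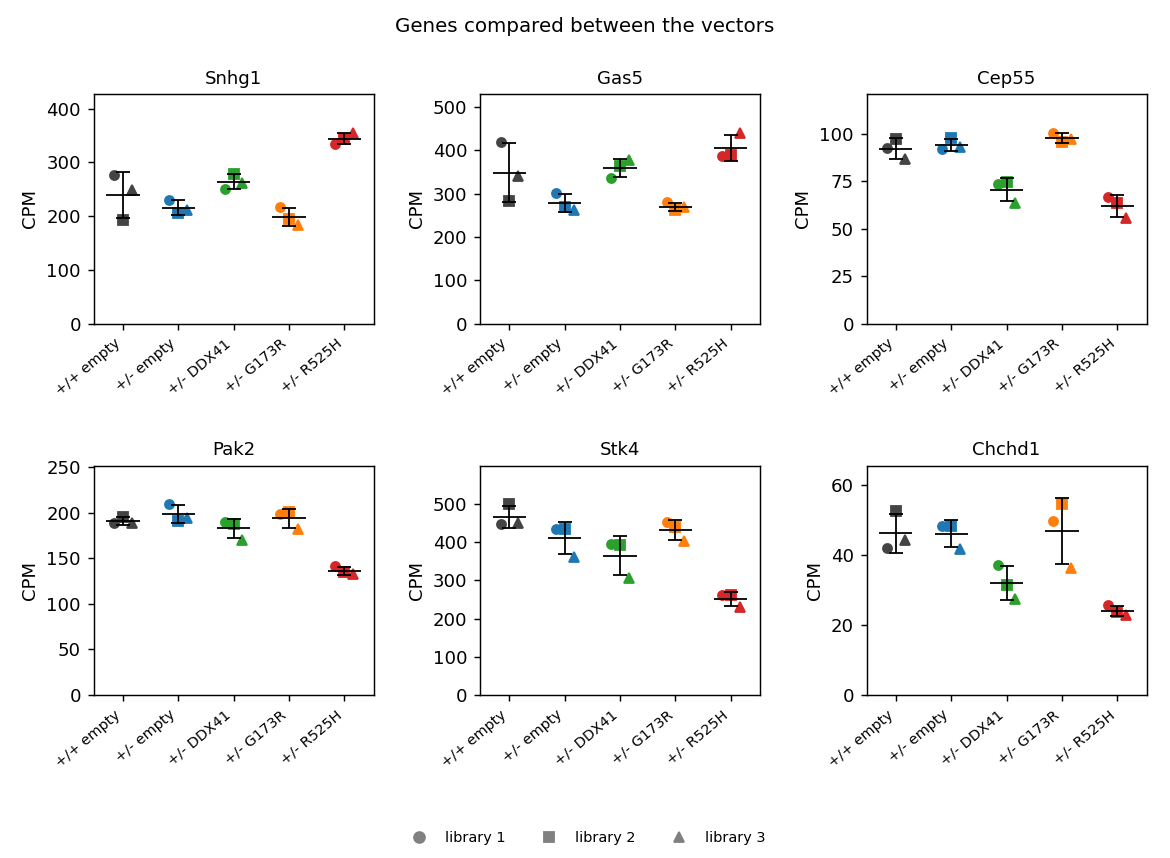
CPM of 6 genes in each library of the 5 groups; horizontal bars are means and error bars SD of 3 libraries. Snhg1 averages 344 CPM in Het R525H and 198 in Het G173R, and Cep55 62 and 97.7.

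In the comparison of G173R with R525H 930 genes had an unadjusted p under 0.05; voom called 8, DESeq2 115, the replicate block 141 (85 higher, 56 lower) and edgeR 38 in libraries 1 and 2 alone. All 12 genes called without the block were called with it. No gene passed without Het G173R 1 or 2 or Het R525H 2 or 3, and 4 passed without Het R525H 1 and 8 without Het G173R 3. A fit of only the 6 libraries called 0. Without Het G173R 3 the ribosome biogenesis, spliceosome and antigen presentation lists had 0.802, 0.802 and 0.231. Without Het R525H 2 the lymphoid and antigen presentation lists had 0.148 and 0.088, and without Het R525H 1 the latter had 0.0851.

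Each heterozygous group with a DDX41 vector was also compared with the wild-type line. In edgeR 661 genes changed in Het DDX41 (343 higher, 318 lower), 551 in Het G173R (309 and 242) and 972 in Het R525H (449 and 523). Ddx41 stayed lower, by log2 fold changes of -0.84, -0.83 and -0.88. Without WT empty 1 or Het DDX41 1 or 2 the first count was 399, 416 and 423, and without Het R525H 1 or 2 the last was 604 and 632. Across the 4 heterozygous groups 410 genes were called against WT empty, all with the same sign in each group (231 higher, 179 lower), where 4 independent lists would share 0.00761 genes. The 4 groups are 1 line, so their lists are not independent and the value of 0.00761 is no measure for them. The 4 comparisons share the 3 WT empty libraries, which are too few to split, so part of this overlap may come from the shared controls; 10 simulations of unchanged groups gave an overlap of 0. Simulated groups without effects leave out the differences between the lines, so this 0 is no measure of what the shared controls add here.

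A reversal by the vectors was tested on the 532 genes that differed between Het empty and WT empty. None passed in the opposite direction with DDX41, G173R or R525H in edgeR. The median fraction of the change undone was 0.0163, 0.0119 and -0.0083 (quartiles -0.0676 to 0.12, -0.0454 to 0.0902 and -0.145 to 0.0883), and 0.5 or more of the change was undone in 6, 4 and 16 genes. In Het DDX41 464 of the 532 genes were still called against WT empty with the same sign. The share with the opposite sign was 55.26 percent (95 percent interval 50.92 to 59.54), 54.89 (50.55 to 59.17) and 46.24 (41.94 to 50.58). These binomial intervals treat the 532 genes as independent, which genes of the same libraries are not. They do not measure the spread between libraries. In 20 simulations with unchanged vectors, where the shared Het empty libraries alone give opposite signs, the mean was 66, 65.4 and 65.8 percent. All 3 measured shares lay below the lowest simulated ones (63.1, 62.2 and 62.1 percent); the simulated libraries are independent, unlike these, and are no measure of what unchanged vectors would give here. Without Het empty 3 the shares were 64.05, 66.45 and 54.9 percent, each above its binomial interval, and 1 gene passed in the opposite direction with R525H. In the F test over the 5 groups 538 genes differed (353, 326 and 339 without WT empty 1, 2 or 3), and 2 among the 4 heterozygous groups.

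**Figure D4:**
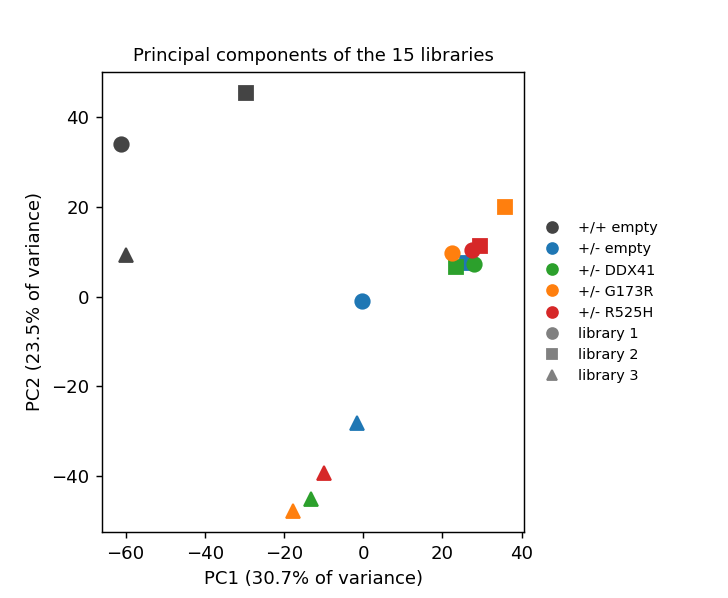
First against second principal component of log2 CPM for the 15 libraries, coloured by group with marker shapes for library number. The components hold 30.7 and 23.5 percent of the variance. In deviations from the group mean, 13 of 15 libraries correlate best, on average, with libraries of their own number in the other groups.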

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

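The test of the 12 genes in the libraries with wild-type DDX41 was chosen after the result was seen; the Ddx41 test and the splits were planned. The effects of G173R and R525H against the same empty-vector libraries differed for 12 genes in the direct comparison in edgeR, which is what set this result apart: Snhg1, Clk3, Hbs1l and Tlr4 were higher with R525H, and Chchd1, Stk4, Ptprs, Cep55, Aebp1, Pak2, Man2c1 and Cc2d1b lower. Of the 10 splits of these 6 libraries the real one gave 12 genes and the highest other 1, and 1 split of 10 reached as many; of the other splits that part all 3 numbered pairs the highest gave 0. These 10 splits are too few for a share under 0.05.

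Names of 12 deposited files carry the code of another group than the sample title, and under those codes the libraries labelled Het G173R would hold empty vector, those labelled Het R525H wild-type DDX41, and those labelled Het empty and Het DDX41 other DDX41 vectors. The comparison of the lines, the reversal and each comparison with empty vector would then mean something else; of the comparisons with WT empty, Het empty gave 532 genes and Het G173R 551. If the libraries labelled Het G173R were the empty-vector ones, Ddx41 could be lowest in them, but its log2 difference from Het empty was 0.13 (95 percent interval -0.11 to 0.38), and no heterozygous group differed in Ddx41, so this leaves the question open, as vector transcripts may not be counted under the gene. Of the 12 genes, 11 had the same sign in Het DDX41 minus Het empty as in Het R525H minus Het G173R (all but Tlr4), with a median log2 difference of 0.17 against 0.6 and a fry p of 0.000556; for Cep55 the means were 94.3 and 70.5 CPM and for Snhg1 216 and 264, and none of the 12 passed there. With the 141 genes called with the replicate block, 90 had the same sign with a median of 0.05, and fry over these genes gave 0.11. Of 10000 random lists of like expression 0 reached as high a median for either set, but such lists do not keep the correlation between genes. Some of the genes also differed between these vectors. Stk4, Pak2 and Ptprs were lower with R525H than with wild-type DDX41 among the 59 genes that passed with the replicate block. With no block none passed, but without Het DDX41 3 Stk4 and Pak2 did (log2 -0.63 and -0.45, edgeR adjusted p = 0.0449 each). Leaving out any other library of Het R525H or Het DDX41 let no gene pass. The R525H libraries helped choose the 12 genes, so extreme values in them are expected in part from the choice. Neither these values nor the smaller median in Het DDX41 minus Het empty tells whether the extent differs. A candidate explanation is that wild-type DDX41 and R525H move most of the 12 genes in the same direction relative to empty vector and G173R. This remains a hypothesis, and what the exchanged codes would predict for these genes was not tested; reads over the vectors' own DDX41 sequence and the 2 changed codons would tell which libraries hold which vector, and Cep55 and Snhg1 measured in new infections of both lines would test it.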

How the results depend on the processing

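Alternatives set before the data were examined were run for the gene counts, Ddx41, the named genes and the reversal; list tests were run only with an estimated correlation, fry, the replicate block and each library left out, and the 2-fold limit only on the counts of genes in the comparisons of 2 groups. The fit of replicates 1 and 2 alone and the DESeq2 likelihood ratio test were added after seeing the data. The DESeq2 Wald test has no single contrast for the 5 groups and was not run there, nor was the fit of 6 libraries. The 58 calls on named genes all held with the replicate block and in DESeq2, 53 with voom, 57 in replicates 1 and 2 alone and 42 in the fit of only the 6 libraries compared; leaving out 1 library ended the call in 98 of 348 fits. DESeq2 size factors in edgeR left the counts of all 11 comparisons within 1.5 times, as did voom. Of the 49 list calls 48 held with the block, 7 with fry and 1 with an estimated correlation. Depth limits the genes with almost no counts in 1 line: with 0 counts the fold is a bound set by 3 counts, and with 1 to 3 it is a ratio with a wide interval. For each value below, the cause was not tested except where fewer libraries or a stricter limit were used.

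With the replicate block 1352 genes changed between Het empty and WT empty, 63 for R525H against empty vector, 1 and 59 for G173R and R525H against DDX41, 141 for G173R against R525H, and 1887, 1453 and 2522 for Het DDX41, Het G173R and Het R525H against the wild-type line. The blocked F test gave 1762, and 2 genes passed in reversal with R525H. Without pairing support, the block is a check only for DDX41 and R525H against empty vector and the comparisons of vector groups with the wild-type line; it changed no other count by more than 1.5 times. In replicates 1 and 2 alone these counts were 1068, 19, 1, 14, 38, 1307, 1133 and 1904, with 1062 in the F test and 1 in reversal with R525H.

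In DESeq2's Wald test the counts were 804 between the lines, 3, 2 and 60 for DDX41, G173R and R525H against empty vector, 3 and 35 for the substitutions against DDX41, 115 between the substitutions, and 1053 and 840 for Het DDX41 and Het G173R against the wild-type line, with 2 and 3 genes in reversal with G173R and R525H. The likelihood ratio test gave 1153. With a log2 fold change above 1 they were 326 between the lines, 0 for R525H against empty vector, 0 between the substitutions, and 374, 352 and 440 against the wild-type line. For R525H against empty vector, upper quartile factors gave 12, no filter 5 and at least 1 CPM in 3 libraries 12; for R525H against DDX41 upper quartile factors gave 1 and the stricter filter 6. Only the 6 libraries compared gave 0 for R525H against empty vector, 0 between the substitutions, and 396, 278 and 610 against the wild-type line. The Ddx41 difference of G173R from DDX41 turned sign with voom (-0.01) and with no filter (0).

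Leaving out 1 library gave 0 to 3 genes for R525H against empty vector, 0 to 2 for R525H against DDX41, 0 to 8 between the substitutions, 399 to 547 and 604 to 754 for Het DDX41 and Het R525H against the wild-type line, 326 to 597 in the F test and 0 to 1 in reversal with R525H. The Ddx41 difference ran from -0.07 to 0.12 for G173R and -0.10 to 0.02 for R525H against DDX41, and -0.02 to 0.17 between the substitutions. The adjusted p of list tests whose direction turned ran from 6.61e-08 to 0.518 for ribosomal protein genes between the lines. For DDX41 against empty vector it ran from 4.78e-05 to 0.947 for glycolysis and 1.91e-06 to 0.345 for cholesterol genes. For G173R against empty vector it ran from 0.000279 to 0.992 for mitosis, 4e-10 to 0.0558 for ribosome biogenesis, 1.66e-07 to 0.897 for ribosomal protein and 2.29e-06 to 0.638 for cholesterol genes. For G173R against DDX41 it ran from 0.000289 to 0.847 for mitosis, 5.05e-09 to 0.712 for spliceosome and 6.45e-09 to 0.468 for histone genes, and for R525H against DDX41 from 0.00129 to 0.677 for spliceosome genes.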

Other observations

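The tests on the third libraries, on the extent of the reversal and on genes with counts in 1 line were chosen after the results were seen; those on the chromosome of Ddx41, on whole chromosomes and on splits were planned. Libraries numbered 3 differed from libraries 1 and 2 in every group: with the group as a term, edgeR called 6707 of 14548 genes (3070 higher, 3637 lower in the third libraries). Of the 532 genes called between Het empty and WT empty 212 were among them, a smaller share than over all genes tested. Lists of metabolism and stress went both ways. Higher were 21 of 22 glycolysis and hypoxia genes (Ldha, lactate dehydrogenase, 2340 ± 293 against 1680 ± 229 CPM; Bnip3 and Egln3, hypoxia targets, by log2 1.03 and 0.81), 19 of 20 cholesterol synthesis genes (Hmgcs1 438 ± 68 against 234 ± 8.63), 16 of 22 p53 targets and 12 of 18 stress response genes; of 10 heat shock genes 7 were lower and 1 higher (list adjusted p = 0.00258), and of 13 mitochondrial mRNAs 6 were lower (0.0521). Scd1, a fatty acid desaturase, was 191 ± 34.2 against 46.5 ± 7.94 CPM (adjusted p = 3.29e-12) and Atf3 17.6 ± 7.4 against 4.07 ± 0.795. Of 18 neutrophil granule genes 10 were lower (Mpo, myeloperoxidase, 757 ± 116 against 1680 ± 353 CPM, and Elane by log2 -1.62) and 3 higher. Lower, too, were 21 of 27 S phase and 24 of 30 ribosome biogenesis genes. Against the direction of their lists, 1 cholesterol, 2 p53 and 2 stress response genes were lower. With an estimated correlation the glycolysis, cholesterol, p53, stress, heat shock, mitochondrial, neutrophil, S phase and ribosome biogenesis lists had adjusted p = 0.234, 0.234, 0.208, 0.208, 0.344, 0.51, 0.245, 0.351 and 0.369.

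A day or batch shared by libraries of the same number stays open: the lowest correlation of deviations over the 10 pairs of libraries numbered 3 was 0.358, which restates that they stand apart and is no test of the cause. Library size is argued against: the totals of 4 of the 5 libraries numbered 3 lay within the range of the other libraries. No biological explanation was tested, as the labels give no day, passage or density. In the F test over 5 groups 3 of 100 groupings, the real one with 538 genes among them, gave as many genes, a share under 0.05. The other two gave 1052 and 882 genes and each put 3 libraries numbered 3 in 1 group. A split that calls more genes than the real one points to a structure of the samples, but of the 13 groupings with 3 such libraries in 1 group 10 gave 0 genes and 1 gave 32, so this placing alone does not give a large count. The drawn groupings that kept the 3 WT empty libraries in 1 group gave 505 and 348 genes. Much of the real count of 538 therefore does not depend on how the heterozygous libraries were grouped. The blocked F test gave 1762.

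The genes that differ between the heterozygous and wild-type lines may reflect the loss of 1 copy of Ddx41 or other differences between 2 separately made lines. A reversal of 0.5 or more of the change by wild-type DDX41 within 2 days is argued against for the groups as titled: the median fraction undone was 0.0163, with 95 percent of the genes below 0.335, while a small reversal is neither seen nor excluded (55.26 percent had the opposite sign, 64.05 without Het empty 3, against a mean of 66 percent and 0.075 undone in simulated unchanged groups, which are independent as these libraries are not), and without a detected rise of Ddx41 this does not exclude its loss as the cause. A gained or lost chromosome is argued against: with Y left out, the largest chromosome median of log2 fold change in size was -0.031. The 7 genes tested on Y had a median of -0.036. On the chromosome of Ddx41 lay 4.9 percent of the called genes (26 of 624 tested there). A segment carried along with the targeted gene therefore does not hold most of the called genes. Whether such a segment holds a few of them was not tested, as no coordinates were used. Differences that do not depend on Ddx41 cannot be told apart from the genotype with 1 line each; 25 called genes, such as Pja1 and Trim6, had 3 counts or fewer in 1 line, and 16 of the 20 with almost no counts in WT empty lay above 0.5 CPM in all 12 heterozygous libraries. Of the 10 splits of the 6 empty-vector libraries 1 gave as many genes as the real 532, the highest other gave 0, also among those that part all 3 pairs, and these splits are too few for a share under 0.05.

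The splits of the remaining comparisons are also too few for a share under 0.05. For DDX41 and for G173R against empty vector 10 of 10 splits gave as many genes as the real 0, with the highest other at 0 and 1. For R525H against empty vector 1 split gave as many as the real 2, with the highest other at 0. For G173R and for R525H against DDX41 10 of 10 gave as many as the real 0, with the highest other at 0 for both.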
